A study of Mus musculus with 6 samples.

How the data were processed

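Gene expression was measured by bulk RNA sequencing in 6 libraries of 4T1 cells, 3 treated with 10 µM cepharanthine (CEP) for 12 h and 3 given the same volume of DMSO. The library source label names single cells, but the protocols and the table of 6 columns describe bulk RNA, and the data were treated as bulk. Samples were assigned to groups and replicate numbers from their titles. Per the labels' protocols, total RNA was extracted with Trizol, RNA with an integrity number above 7 was accepted, poly(A) RNA was selected on oligo(dT) beads and fragmented, and libraries were made with the TruSeq Stranded mRNA kit, with dUTP in the second strand. Replication-dependent histone transcripts and other RNAs without poly(A) tails were therefore depleted. The deposited table held whole-number counts of reads per Ensembl gene for each of the 6 libraries, not normalised, with gene coordinates on GRCm38.p6 per the file headers. HISAT2, HISAT, HTSeq and DESeq2 and the build GRCm38 are named in the submitters' processing notes, with no role or order. The strand setting used for counting, the annotation release, read filters and tool versions are not given in the sources used here. Counting without strand could add reads of overlapping genes on the opposite strand, or drop reads shared by both genes, depending on the counter. HTSeq-type counting can also drop reads that match several genes, which lowers counts of near-identical paralogs and of genes with pseudogene copies. The table held no row without a gene, and 115 symbols were shared by several genes (236 genes), which were kept apart by Ensembl identifier.

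Total counts ran from 15299261 to 19655010 per library, and intervals for counts given here cover counting error only. Genes were kept with edgeR filterByExpr (minimum count 10, minimum total 15), scaled with TMM and tested with edgeR's quasi-likelihood test (estimateDisp, robust glmQLFit, glmQLFTest) with the group as the only term, CEP minus DMSO. P-values were adjusted with the Benjamini-Hochberg method over the 13405 genes tested, and an adjusted p under 0.05 counted as changed, with a further count at 2-fold or more. Fold changes are log2, ± SE, and CPM are TMM-scaled means ± SD (n = 3). This SE was back-calculated as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. Gene lists were tested with limma camera on the edgeR object with a preset correlation of 0.01, adjusted over the 34 lists with at least 3 tested members. Of 783 distinct list genes, 754 matched by the table's own symbol, 28 through an older symbol and 1 did not match. Single values per library were compared with an exact two-sided permutation test over 20 assignments, whose smallest p is 0.1. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15.

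The design, the lists, the alternatives to be tried and the rule for named genes were set before the data were examined. Under that rule the text names the 10 largest rises and 10 largest falls among changed genes with no overlap between the groups, a mean of at least 5 CPM and an official symbol. It also names a panel of 16 genes whether or not they passed, and per list up to 3 members with the smallest adjusted p in each direction, at most 4 per list. Some genes stand in several lists, which are therefore not independent. Results of some genes under this rule are not reported here. Ephb4, and the genes named in the closing section's added lists, were chosen after their values were seen. The alternatives set then were other scaling (RLE, upper quartile, library totals), DESeq2 and limma-voom, other low-count filters (none, 1 CPM in 3 libraries, mean of 5 CPM), the replicate number as a block, each library left out, a threshold of 0.01, protein-coding genes only, and, for lists, an estimated correlation, fry and cameraPR. For the lists, the DESeq2 alternative was camera on limma-voom values. Leaving out mitochondrially encoded genes and removing per-library trends with exon length and GC content (loess span 0.5, GC from GENCODE mouse release 21) were added after the data were seen. Overlaps of exons were also taken from that release.

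Before use, the gene test was tested on simulated counts for the same 13405 genes with 200 changed. It recovered 52% of genes changed 1.25-fold, 62% at 1.5-fold, 90% at 2-fold and 96% at 4-fold, and 9 of 159 calls (5.66%) were of unchanged genes. Far fewer genes changed there than were called in the data, and genes were drawn independently, so these shares do not carry over. Replicates were compared in pairs by a chi-square test of counts over genes with a summed count of at least 20. Chi-square per degree of freedom ran from 1.81 (DMSO replicates 2 and 3) to 10.9 (CEP replicates 1 and 3), so no pair agreed within sampling noise. That excess does not tell separate cultures from technical preparations of 1 culture. Each library was counted as 1 replicate. No sample or column was left out.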

Results

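Poly(A)-selected RNA was sequenced from 4T1 cells, a transplantable mammary carcinoma line derived from a BALB/c mouse. The cells had been kept for 12 h with 10 µM cepharanthine (CEP) or with the same volume of dimethyl sulfoxide (DMSO), the solvent control. Cepharanthine is a weakly basic, amphiphilic bisbenzylisoquinoline alkaloid from Stephania plants. There were 3 libraries per group, and the comparison asked which transcripts differed in level between treated and solvent-exposed cells. Counts summed over genes were 19411816, 15299261 and 17025734 in CEP replicates 1, 2 and 3, and 16855636, 15334482 and 19655010 in DMSO replicates 1, 2 and 3. The group means were 17245600 ± 2065070 and 17281700 ± 2191550 (SD, n = 3 each, exact two-sided permutation p = 0.9), so depth did not separate the groups. Of 55487 genes in the table, 29576 had 0 counts in all 6 libraries and 13405 were tested, 11525 of them protein coding.

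Cepharanthine-treated cells had higher levels of transcripts of lysosomal genes, of the vacuolar proton pump, of the ATF4 and CHOP stress response and of inflammatory and interferon-response genes. Lower levels were found for transcripts of DNA replication, mitosis, ribosome biogenesis, nuclear-encoded respiratory chain and proteasome genes. These lists passed camera with a preset correlation, but none of the 34 lists tested passed it with an estimated correlation (7 had an unadjusted p under 0.05). The largest rises included Gpnmb, which encodes a glycoprotein of lysosomal membranes, with 543 ± 86.2 CPM in CEP and 84.2 ± 6.08 CPM in DMSO (log2 fold change 2.69 ± 0.127, SE). Acod1, which encodes the enzyme that makes itaconate, rose by 3.03 ± 0.206 on the log2 scale, and Cxcl2, a chemokine that attracts neutrophils, rose by 2.94 ± 0.153. The stress-induced transcription factor genes Atf3 and Ddit3 (CHOP) rose by 2.20 ± 0.125 and 1.95 ± 0.135, and Zfand2a, an arsenite-inducible gene of proteasome handling, rose by 2.28 ± 0.0758. Among the falls were Apcdd1, an inhibitor of Wnt signalling (-1.13 ± 0.0826, from 72.0 ± 3.84 CPM in DMSO to 32.8 ± 4.24 CPM in CEP), Sorbs3, which encodes the adhesion protein vinexin (-1.59 ± 0.205), and Mgp, which encodes matrix Gla protein (-1.21 ± 0.134).

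In total 5125 of 13405 genes changed, 2691 higher and 2434 lower with CEP, which was 38.2% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median absolute log2 fold change of the changed genes was 0.35, and 389 genes changed at least 2-fold, 327 higher and 62 lower. The 3 CEP and 3 DMSO values did not overlap for 6683 of the 13405 tested genes (49.9%), where chance would give 10%. The biological coefficient of variation was 6.07%. On principal component analysis the first component held 60.7% of the variance and separated the groups, with scores of 10.1, 28.5 and 30.4 for CEP replicates 1, 2 and 3 against -21.9, -23.2 and -23.8 for the DMSO replicates. CEP replicate 1 stood apart from the other CEP libraries. Without it, 6905 genes changed and 659 changed at least 2-fold. Where a call below is said to have ended or appeared under another setting, the adjusted p there is followed by the range over all alternatives tried.

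**Figure D1:**
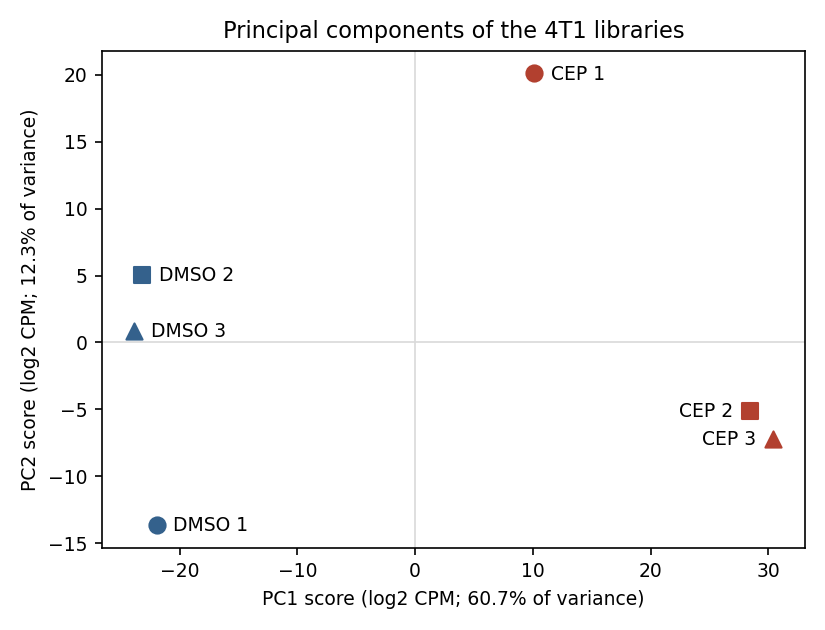
Principal component scores (log2 CPM scale) of the 3 CEP and 3 DMSO libraries, 1 point per library, on the first component (60.7% of variance) and the second (12.3%). CEP replicate 1 lies at 10.1 on the first component, between the DMSO libraries near -23.2 and the other CEP libraries at 28.5 and 30.4.

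The 10 largest rises and 10 largest falls among genes with a mean of at least 5 CPM and no overlap between the groups are given here on the log2 scale. Zan, a sperm membrane protein gene, rose by 3.44 ± 0.223, but its exons overlap those of Ephb4 on the opposite strand. Ephb4, looked up for this overlap, itself rose by 0.52 ± 0.0464. It was more abundant, at 264 ± 7.31 CPM in CEP and 184 ± 5.40 CPM in DMSO. A constant share of Ephb4 reads counted as Zan would also rise by 0.52. The larger rise of Zan argues against such reads as its whole source, and other sources were not tested. Lilr4b, a receptor gene with a near-identical paralog, rose by 3.33 ± 0.145, and the lipoxygenase gene Aloxe3 rose by 2.90 ± 0.229. The lysosomal hyaluronidase gene Hyal1, which overlaps Hyal3 and Naa80 on the same strand, rose by 2.26 ± 0.273. Falls were -1.26 for Asb2, -1.25 for Hacd4, -1.20 for Gbp4, -1.11 for M1ap, -1.08 for Add2, -1.06 for Adamts8 and -1.05 for Carns1. Adjusted p-values of these 20 genes ran from 5.97e-10 for Zfand2a to 0.00563 for M1ap (edgeR quasi-likelihood test, Benjamini-Hochberg). In the authors' annotation (GRCm38.p6), Gpnmb is ENSMUSG00000029816, chromosome 6, 49036546 to 49070929, Acod1 is ENSMUSG00000022126, chromosome 14, 103046977 to 103056573, and Cxcl2 is ENSMUSG00000058427, chromosome 5, 90903871 to 90905938. Atf3 is ENSMUSG00000026628, chromosome 1, 191170296 to 191218039, Ddit3 is ENSMUSG00000025408, chromosome 10, 127290774 to 127296288, and Apcdd1 is ENSMUSG00000071847, chromosome 18, 62922231 to 62961179.

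**Figure D2:**
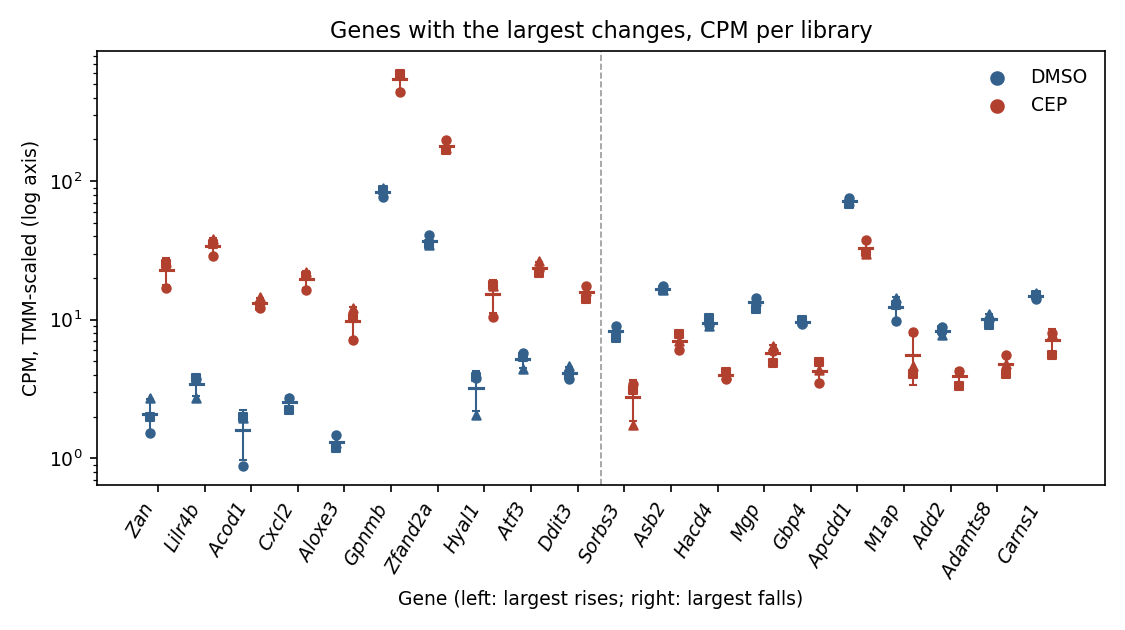
CPM (TMM-scaled, log axis) of the 10 genes with the largest rises and the 10 with the largest falls, with 1 point per library (circle, square and triangle for replicates 1, 2 and 3) and group mean ± SD. Gpnmb reached the highest level of these genes, 543 CPM with CEP against 84.2 CPM with DMSO.

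Genes of the lysosome, the acidic compartment that degrades macromolecules, rose together. Of 32 tested members 27 rose, 0 fell and 5 did not pass. 27 rose and 0 fell adjusted over the list alone, with a median log2 fold change of 0.64 (camera adjusted p = 1.23e-30, and adjusted p = 0.139 with an estimated correlation). Tpp1, which encodes a lysosomal peptidase, rose by 1.16 ± 0.0654, Gla, which encodes alpha-galactosidase A, rose by 1.67 ± 0.0960, and Npc1, whose product exports cholesterol from lysosomes, rose by 1.22 ± 0.0787. Each of the 15 tested genes of the vacuolar proton pump, which acidifies lysosomes, rose. 15 rose and 0 fell when adjusted over the list alone, with a median of 0.70 (camera adjusted p = 8.57e-21, and adjusted p = 0.0663 with an estimated correlation). Its subunit gene Atp6v0b rose by 1.22 ± 0.0738 and Atp6v1d by 0.85 ± 0.0549. In the list of phospholipid and bis(monoacylglycero)phosphate handling, 10 rose, 0 fell and 2 did not pass of 12 tested. With p adjusted over the list alone, 11 rose and 0 fell (median 0.59, camera adjusted p = 4.59e-14, and adjusted p = 0.0663 with an estimated correlation). Asah1, which encodes acid ceramidase, rose by 0.70 ± 0.0585, and Lamp2, a lysosomal membrane protein gene, by 0.82 ± 0.0671. These genes, Npc1 and Npc2 stand also in the lysosome list. Of 30 autophagy genes 17 rose, 1 fell and 12 did not pass. The counts were 19 higher and 1 lower adjusted over the list alone (median 0.26, camera adjusted p = 2.75e-07, and adjusted p = 0.0834 with an estimated correlation). Sqstm1, the gene of the autophagy receptor p62, rose by 1.35 ± 0.0535 to 1215 ± 55.7 CPM, Tecpr1 rose by 1.02 ± 0.0755, and Map1lc3b (LC3B) rose by 0.64 ± 0.0507, while Atg3 fell (-0.38 ± 0.0921).

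Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, also rose. Of 30 tested 21 rose, 2 fell and 7 did not pass. Testing adjusted over the list alone gave 23 higher and 2 lower, with a median of 0.45 (camera adjusted p = 1.79e-15, and adjusted p = 0.139 with an estimated correlation). Chac1, a glutathione-degrading enzyme gene, rose by 1.70 ± 0.0614 and Trib3 by 1.08 ± 0.0780. The members that fell were Phgdh (-0.19 ± 0.0490) and Wars (-0.16 ± 0.0480). Phgdh did not pass without DMSO replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0652, alternatives 8.77e-06 to 0.0652), and Wars did not pass without CEP replicate 2, CEP replicate 3 or DMSO replicate 3 (adjusted p = 0.0719, 0.0553 and 0.0802, alternatives 5.61e-05 to 0.0802). Chaperone and degradation genes of the endoplasmic reticulum (ER) numbered 23, of which 9 rose, 1 fell and 13 did not pass. Higher were 9 and lower 1 adjusted over the list alone (median 0.06, camera adjusted p = 0.0150, and adjusted p = 0.346 with an estimated correlation). That call ended with cameraPR on ranks (adjusted p = 0.0659, alternatives 0.00159 to 0.346). With CEP replicate 1 left out, 11 ER genes rose and 4 fell. Herpud1 and Dnajb9, of ER-associated degradation and ER folding, rose by 1.04 ± 0.0693 and 0.96 ± 0.0941. Hspa5, the main ER chaperone gene, did not pass at 0.12 ± 0.0647 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.166), but did without CEP replicate 1 (0.17, adjusted p = 3.07e-04), and stood at 0.05 without CEP replicate 3 (adjusted p = 0.588, alternatives 3.07e-04 to 0.588). Sec61b fell (-0.21 ± 0.0577), a call that ended without DMSO replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0685) and after removal of length and GC trends (0.0818, alternatives 0.00112 to 0.0818).

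Heat shock genes went both ways. Of 16 tested 6 rose, 3 fell and 7 did not pass. Adjusted over the list alone, 6 rose and 3 fell (median 0.03, camera adjusted p = 0.396, and adjusted p = 0.624 with an estimated correlation). The cytosolic chaperone genes Hspa1b, which has a near-identical paralog, and Hspa4l rose by 0.79 ± 0.0825 and 0.54 ± 0.0612, and the mitochondrial chaperone genes Hspd1 and Hspe1 fell (-0.39 ± 0.0559 and -0.41 ± 0.0680). Of 22 targets of NRF2, the regulator of antioxidant genes, 3 rose, 5 fell and 14 did not pass. 3 rose and 5 fell adjusted over the list alone (median -0.02, camera adjusted p = 0.708, and adjusted p = 0.845 with an estimated correlation). Without CEP replicate 1, 5 heat shock genes and 8 NRF2 targets fell. With 1 library left out, the heat shock median ran from -0.0370 (without CEP replicate 1) to 0.0874 (without CEP replicate 3), and the NRF2 median from -0.0902 to 6.59e-04 without the same libraries. Hmox1, the haem oxygenase gene, rose by 0.77 ± 0.0665, Ftl1 by 0.38 ± 0.0505 and Slc7a11, the cystine transporter gene, by 1.29 ± 0.204, while Gclm of glutathione synthesis fell (-0.34 ± 0.0570). Genes tied to ferroptosis, an iron-dependent form of cell death, rose more often than they fell: of 17, 10 rose, 2 fell and 5 did not pass. With p adjusted over the list alone, 10 rose and 2 fell (median 0.27, camera adjusted p = 1.49e-07, and adjusted p = 0.0663 with an estimated correlation). Of those that rose, Chac1 and Slc3a2 stand also in the ATF4 list, Hmox1 and Ftl1 in the NRF2 list, Slc7a11 in both, and Ptgs2 in the NF-kB list, so this list repeats part of the others. Those that fell were Dhodh (-0.45 ± 0.0931) and Ncoa4 (-0.23 ± 0.0629), the latter not past without CEP replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0609, alternatives 7.41e-05 to 0.0609). Of 5 genes of metallothioneins and zinc transport, 2 rose, 0 fell and 3 did not pass. The counts were 2 higher and 0 lower adjusted over the list alone (median 0.34, camera adjusted p = 0.0838, and adjusted p = 0.331 with an estimated correlation). Mt1 rose by 0.64 ± 0.0631 and the zinc importer gene Slc39a10 by 0.34 ± 0.0578. By camera or fry adjusted p, the list passed without CEP replicate 2 (0.0412), with no low-count filter (0.0269), after removal of length and GC trends (0.0335) and with fry (0.00683, alternatives 0.00683 to 0.331).

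Cholesterol genes rose modestly. Of 24 genes of cholesterol synthesis and uptake 13 rose, 0 fell and 11 did not pass. Testing adjusted over the list alone gave 13 higher and 0 lower, with a median of 0.23 (camera adjusted p = 2.20e-04, and adjusted p = 0.331 with an estimated correlation). The sterol synthesis enzyme genes Msmo1 and Cyp51 rose by 0.55 ± 0.0528 and 0.48 ± 0.0516, Srebf2, the gene of their master regulator, by 0.31 ± 0.0448 and Insig1 by 0.28 ± 0.0536. Of 14 fatty acid synthesis genes 6 rose, 1 fell and 7 did not pass. Higher were 6 and lower 2 adjusted over the list alone (median 0.08, camera adjusted p = 0.206, and adjusted p = 0.409 with an estimated correlation). Without CEP replicate 1, 3 fell. The elongase gene Elovl6 rose by 0.33 ± 0.0464, Acsl3 by 0.33 ± 0.0548 and Mid1ip1 by 0.45 ± 0.0780. Gpam fell (-0.24 ± 0.0850), a call that ended without CEP replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.186), without DMSO replicate 1, 2 or 3 (0.0684, 0.0573 and 0.183), with DESeq2 (0.0612) and with the replicate number as a block (0.0574, alternatives 0.00332 to 0.186). Of 6 tested genes in the list of cholesterol efflux, LXR targets and LXR genes themselves, 3 rose, 0 fell and 3 did not pass. Adjusted over the list alone, 3 rose and 0 fell (median 0.23, camera adjusted p = 0.154, and adjusted p = 0.331 with an estimated correlation). Apoe rose by 0.84 ± 0.171 and Nr1h2, which encodes LXR-beta, by 0.27 ± 0.0512. Abca2 rose by 0.18 ± 0.0522, but not past the test without CEP replicate 3, DMSO replicate 2 or DMSO replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0740, 0.0620 and 0.0628) or after removal of length and GC trends (0.70, alternatives 0.00399 to 0.70). With fry, which asks only whether a list's genes move one way on balance, the fatty acid and efflux lists passed (fry adjusted p = 0.0159 and 0.00349).

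Of 28 NF-kB targets and inflammatory cytokine genes 22 rose, 1 fell and 5 did not pass. 24 rose and 1 fell adjusted over the list alone, with a median of 0.74 (camera adjusted p = 8.57e-21, and adjusted p = 0.0663 with an estimated correlation). The neutrophil chemokine gene Cxcl1 rose by 1.39 ± 0.0563, to 395 ± 23.6 CPM in CEP and 151 ± 7.75 CPM in DMSO, and Csf3, which encodes the granulocyte growth factor G-CSF, by 0.89 ± 0.0601. Vcam1, an adhesion molecule gene, fell (-0.46 ± 0.0685). Immediate early genes were mixed: of 25, 12 rose, 4 fell and 9 did not pass. With p adjusted over the list alone, 12 rose and 5 fell (median 0.42, camera adjusted p = 3.53e-04, and adjusted p = 0.331 with an estimated correlation). The phosphatase gene Dusp4 rose by 0.83 ± 0.0483, while Dusp6, a phosphatase gene induced by ERK signalling, and Egr3 fell (-0.90 ± 0.0547 and -0.84 ± 0.177). This list did not pass without CEP replicate 1 (camera adjusted p = 0.0805, alternatives 1.53e-06 to 0.331, with 8 members that fell), and its median was 0.24 without DMSO replicate 1. Its mean in CEP replicates 1, 2 and 3 stood 0.36, 0.07 and 0.14 above the DMSO mean on the log2 scale, overlapping the DMSO libraries.

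Genes of the type I interferon response rose: of 28 tested 17 rose, 0 fell and 11 did not pass. The counts were 21 higher and 0 lower adjusted over the list alone, with a median of 0.67 (camera adjusted p = 1.64e-07, and adjusted p = 0.331 with an estimated correlation). Oasl1 and Ifit1 of this list rose by 1.15 ± 0.0781 and 1.03 ± 0.128, and the chemokine gene Cxcl10 by 1.76 ± 0.179. The rise was unequal among the CEP libraries. The list's mean log2 CPM stood 0.27, 0.87 and 0.78 above the DMSO mean in CEP replicates 1, 2 and 3. In the same order that of 18 MHC class I genes stood 0.08, 0.33 and 0.33 above it, and that of the checkpoint list 0.28, 0.46 and 0.48 above it. Of the MHC class I genes 10 rose, 2 fell and 6 did not pass. Testing adjusted over the list alone gave 10 higher and 3 lower (median 0.34, camera adjusted p = 0.0173, and adjusted p = 0.493 with an estimated correlation). That list did not pass with fry (adjusted p = 0.0538) or with cameraPR on ranks (0.0659, alternatives 1.95e-05 to 0.493). B2m, the MHC class I light chain gene, rose by 0.38 ± 0.0541 and Tapbpl of peptide loading by 0.78 ± 0.0876, while the immunoproteasome subunit genes Psmb10 and Psmb9 fell (-0.35 ± 0.0720 and -0.34 ± 0.126). The Psmb9 call did not hold without CEP replicate 1, 2 or 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.102, 0.0517 and 0.0679) or without DMSO replicate 1, 2 or 3 (0.0770, 0.0948 and 0.15). It also ended with the replicate number as a block (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0547), DESeq2 (0.101), library totals (0.0539), no low-count filter (0.0568) and removal of length and GC trends (0.0676, alternatives 0.0324 to 0.15).

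Of 13 tested checkpoint ligands and surface immune regulators 6 rose, 1 fell and 6 did not pass. Higher were 6 and lower 1 adjusted over the list alone (median 0.26, camera adjusted p = 7.28e-04, and adjusted p = 0.259 with an estimated correlation). Pvr, the poliovirus receptor gene, rose by 1.16 ± 0.0581, Lgals3 (galectin-3) by 1.35 ± 0.0871 and Tnfsf9, the gene of the costimulatory ligand 4-1BBL, by 0.92 ± 0.159. Lgals9 (galectin-9) fell (-0.23 ± 0.0649), not past without CEP replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0669) or DMSO replicate 2 (0.0534, alternatives 9.16e-04 to 0.0669). Cd274, which encodes PD-L1, was near the detection floor at 2.40 ± 0.738 CPM in CEP and 1.26 ± 0.146 CPM in DMSO and rose by 0.90 ± 0.293 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0247). That call ended with DESeq2 (0.0615), without CEP replicate 2 or 3 (0.0854 and 0.127), and without DMSO replicate 1, 2 or 3 (0.0755, 0.0752 and 0.0506, alternatives 0.00111 to 0.127).

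Proliferation genes fell. Of 32 genes of DNA replication and the G1/S transition 2 rose, 22 fell and 8 did not pass. Adjusted over the list alone, 2 rose and 22 fell, with a median of -0.28 (camera adjusted p = 5.30e-07, and adjusted p = 0.331 with an estimated correlation). Tk1, the thymidine kinase gene, fell (-0.41 ± 0.0438), as did Mcm6 of the replicative helicase (-0.40 ± 0.0521). Those that rose were the licensing factor gene Cdt1, by 0.28 ± 0.0540, and Chaf1b, by 0.19 ± 0.0617. Chaf1b did not pass without CEP replicate 1, DMSO replicate 1 or DMSO replicate 2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0740, 0.0865 and 0.107), or with DESeq2 or upper-quartile factors (0.0837 and 0.050, alternatives 0.0137 to 0.107). Of 32 genes of G2/M and mitosis 1 rose, 20 fell and 11 did not pass. 1 rose and 24 fell adjusted over the list alone (median -0.21, camera adjusted p = 5.12e-07, and adjusted p = 0.331 with an estimated correlation). Mki67, the proliferation marker Ki-67, fell (-0.37 ± 0.0557), as did Cdk1 (-0.37 ± 0.0486) and Cenpf (-0.44 ± 0.0518), and Cdc25b rose by 0.27 ± 0.0486. The mitotic cyclin gene Ccnb1 fell less (-0.18 ± 0.050), and its call ended without CEP replicate 2 or 3 or without DMSO replicate 2 or 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0636, 0.0531, 0.0568 and 0.0548, alternatives 3.34e-06 to 0.0636). Relative to the DMSO mean, CEP replicates 1, 2 and 3 stood at -0.14, -0.27 and -0.30 for the replication list and at -0.13, -0.23 and -0.24 for the mitosis list.

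Of 7 cyclin-dependent kinase inhibitor and D cyclin genes 2 rose, 3 fell and 2 did not pass. With p adjusted over the list alone, 2 rose and 3 fell (median -0.07, camera adjusted p = 0.471, and adjusted p = 0.644 with an estimated correlation). All 3 D cyclin genes fell, Ccnd1 most (-0.69 ± 0.126, 1121 ± 221 CPM in CEP and 1808 ± 21.5 CPM in DMSO), followed by Ccnd3 (-0.28 ± 0.0584) and Ccnd2 (-0.21 ± 0.0461), while the inhibitor gene Cdkn1b (p27) rose by 0.31 ± 0.0628 and Cdkn2c (p18) by 0.31 ± 0.0612. Cdkn1a, the p21 gene and a p53 target, did not pass at 0.12 ± 0.0888 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.288), and stood at 0.0047 without CEP replicate 1 (adjusted p = 0.966) and at 0.07 without DMSO replicate 1 (adjusted p = 0.632, alternatives 0.112 to 0.966). The list's median ran from -0.153 without CEP replicate 2 to 0.00470 without CEP replicate 1. Of 21 p53 targets 10 rose, 4 fell and 7 did not pass. The counts were 11 higher and 4 lower adjusted over the list alone (median 0.21, camera adjusted p = 9.45e-04, and adjusted p = 0.227 with an estimated correlation). Mdm2, the gene of the p53 ubiquitin ligase, rose by 0.70 ± 0.0539, Trp53inp1 by 1.65 ± 0.141 and Plk2 by 0.77 ± 0.0697, and Ei24 fell (-0.24 ± 0.0524). Whether p53 drove any of these changes was not tested. Apoptosis regulators moved both ways: of 27, 7 rose, 7 fell and 13 did not pass. Testing adjusted over the list alone gave 9 higher and 7 lower (median 0.12, camera adjusted p = 0.836, and adjusted p = 0.845 with an estimated correlation). Without CEP replicate 1, 11 rose and 9 fell, and the median was 0.06 without CEP replicate 2. The pro-apoptotic gene Bbc3 (PUMA) rose by 0.99 ± 0.134 and Birc3, an inhibitor of apoptosis, by 0.61 ± 0.0704, while the anti-apoptotic gene Bcl2 fell (-0.41 ± 0.0690). This list passed with fry (fry adjusted p = 0.0165, alternatives 0.0165 to 0.913).

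Of 25 MYC targets and ribosome biogenesis genes 0 rose, 19 fell and 6 did not pass. Higher were 0 and lower 19 adjusted over the list alone, with a median of -0.26 (camera adjusted p = 1.97e-07, and adjusted p = 0.331 with an estimated correlation). The nucleolar protein genes Dkc1 and Ncl fell (-0.53 ± 0.0572 and -0.42 ± 0.0628), as did the spermidine synthase gene Srm (-0.69 ± 0.0770). Myc itself did not pass at -0.13 ± 0.0700 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.162), but did without DMSO replicate 1 (-0.22, adjusted p = 0.0102) and with no low-count filter (adjusted p = 0.0494). It stood at -0.07 without DMSO replicate 2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.497, alternatives 0.0102 to 0.497). Relative to the DMSO mean, this list stood at -0.16, -0.33 and -0.32 in CEP replicates 1, 2 and 3. Proteasome subunit genes fell by small amounts: of 27, 0 rose, 17 fell and 10 did not pass. Adjusted over the list alone, 0 rose and 19 fell (median -0.17, camera adjusted p = 7.50e-05, and adjusted p = 0.409 with an estimated correlation). Psma7 and Psma4 of the core particle fell (-0.33 ± 0.0507 and -0.34 ± 0.0616). Of 31 cytosolic ribosomal protein genes, many of which have processed pseudogenes, 0 rose, 16 fell and 15 did not pass. 0 rose and 21 fell adjusted over the list alone (median -0.15, camera adjusted p = 3.46e-04, and adjusted p = 0.409 with an estimated correlation). Without CEP replicate 1, 26 fell. After removal of length and GC trends 4 fell, 1 rose and the list no longer passed (camera adjusted p = 0.0593, alternatives 1.63e-06 to 0.409). Rpl27 fell (-0.24 ± 0.0584), and Rpl11 fell (-0.19 ± 0.0463) but not after that removal (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.103, alternatives 1.13e-05 to 0.103).

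Of 30 nuclear-encoded respiratory chain genes 0 rose, 24 fell and 6 did not pass. With p adjusted over the list alone, 0 rose and 26 fell, with a median of -0.23 (camera adjusted p = 1.64e-07, and adjusted p = 0.331 with an estimated correlation). Sdha and Ndufs1, of respiratory complexes II and I, fell (-0.32 ± 0.0477 and -0.32 ± 0.0494), as did Atp5c1 of the ATP synthase (-0.34 ± 0.0523). Genes encoded by the mitochondrial genome moved the other way: of 12, 8 rose, 0 fell and 4 did not pass. The counts were 9 higher and 0 lower adjusted over the list alone (median 0.48, camera adjusted p = 5.02e-05, and adjusted p = 0.331 with an estimated correlation). The cytochrome c oxidase gene mt-Co1 rose by 0.73 ± 0.0568, mt-Nd4 by 0.48 ± 0.0710 and mt-Cytb by 0.42 ± 0.0823. The list's mean stood at 0.66, 0.31 and 0.56 in CEP replicates 1, 2 and 3 and at 0.30, -0.08 and -0.22 in DMSO replicates 1, 2 and 3, relative to the DMSO mean, so that DMSO replicate 1 lay close to CEP replicate 2. Without CEP replicate 1, 4 rose. Nuclear copies of mitochondrial sequence make these counts uncertain. Mitochondrially encoded genes took 2.64% ± 0.231 of counts in CEP and 1.77% ± 0.134 in DMSO (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest this design allows). Of 19 glycolysis genes 5 rose, 3 fell and 11 did not pass. Testing adjusted over the list alone gave 5 higher and 3 lower (median -0.02, mean 0.07, camera direction upward, camera adjusted p = 0.708, and adjusted p = 0.845 with an estimated correlation). Without CEP replicate 1, 7 fell. The glucose transporter gene Slc2a1 rose by 0.56 ± 0.0545 and Pfkp by 0.40 ± 0.0521, while Eno1 and Ldha fell (-0.30 ± 0.0605 and -0.24 ± 0.0566). Hypoxia-response genes rose: of 19, 12 rose, 0 fell and 7 did not pass. Higher were 13 and lower 0 adjusted over the list alone (median 0.36, and 0.55 without DMSO replicate 2; camera adjusted p = 1.94e-06, and adjusted p = 0.331 with an estimated correlation). Vegfa, the vascular growth factor gene, rose by 1.22 ± 0.109 and the histone demethylase gene Kdm3a by 0.54 ± 0.0646.

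Of 16 epithelial markers 8 rose, 4 fell and 4 did not pass. Adjusted over the list alone, 9 rose and 4 fell (median 0.36, camera adjusted p = 0.0483, and adjusted p = 0.471 with an estimated correlation). The junction genes Dsp (desmoplakin) and Cldn7 rose by 0.71 ± 0.0679 and 0.70 ± 0.0753, while the keratin gene Krt8 and Tjp1 fell (-0.60 ± 0.0564 and -0.36 ± 0.0506). The list call was lost with upper-quartile factors (camera adjusted p = 0.0715), library totals only (0.0864), limma-voom (0.129), a minimum of 1 CPM in 3 libraries (0.0610), a minimum mean of 5 CPM (0.107), cameraPR (0.153), without CEP replicate 3 (0.0511) and without DMSO replicate 1 (0.104, alternatives 2.13e-04 to 0.471). Its mean stood 0.17, 0.36 and 0.35 above the DMSO mean in CEP replicates 1, 2 and 3. Of 21 genes of mesenchymal transition and matrix 4 rose, 6 fell and 11 did not pass. 4 rose and 6 fell adjusted over the list alone (median 0.00, mean -0.10, camera direction downward, camera adjusted p = 0.0307, and adjusted p = 0.331 with an estimated correlation). The protease gene Mmp9 fell (-0.97 ± 0.0555), as did the matricellular protein gene Ccn2 (65.5 ± 2.39 CPM in CEP and 131 ± 12.1 CPM in DMSO), while the integrin gene Itga5 and Mmp14 rose by 0.60 ± 0.0857 and 0.37 ± 0.0598. That call was lost with limma-voom (camera adjusted p = 0.184), with cameraPR (0.352) and without CEP replicate 1 (0.200, alternatives 0.00526 to 0.352), and the median was negative without any 1 library, from -0.12 without DMSO replicate 1 to -0.00422 without DMSO replicate 2.

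Of 13 targets of YAP and TAZ, the coactivators of the Hippo pathway, 2 rose, 6 fell and 5 did not pass. With p adjusted over the list alone, 2 rose and 6 fell (median -0.16, camera adjusted p = 0.00236, and adjusted p = 0.331 with an estimated correlation). Ankrd1 fell (-0.64 ± 0.0583), as did Ccn2. The median was -0.26 without DMSO replicate 1, and the library means of CEP replicates 1, 2 and 3 stood at -0.32, -0.03 and -0.12 relative to the DMSO mean, overlapping the DMSO libraries. Of the genes that rose, F3 (0.43 ± 0.131) did not pass without CEP replicate 2 or DMSO replicate 1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0958 and 0.0901, alternatives 2.59e-04 to 0.0958). Edn1 (1.08 ± 0.377) did not pass without CEP replicate 2 or 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.187 and 0.0713), without DMSO replicate 1, 2 or 3 (0.101, 0.0896 and 0.0797), with DESeq2 (0.106) or with limma-voom (0.0550, alternatives 0.00559 to 0.187). Of 13 genes of drug efflux and xenobiotic metabolism 4 rose, 3 fell and 6 did not pass. The counts were 4 higher and 3 lower adjusted over the list alone (median 0.04, mean 0.03, camera direction downward, camera adjusted p = 0.708, and adjusted p = 0.845 with an estimated correlation). The aldehyde dehydrogenase gene Aldh3a1 fell (-0.81 ± 0.0495), and Tiparp and the transporter gene Abcc4 rose by 0.30 ± 0.0507 and 0.31 ± 0.0651.

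Most markers of other cell types were scarce. Macrophage and granulocyte markers took 0.00482% of counts in CEP and 0.00177% in DMSO, nearly all from Cd68, a lysosomal membrane glycoprotein gene that rose by 1.47 ± 0.135, to 48.1 ± 8.23 CPM in CEP and 17.3 ± 2.29 CPM in DMSO. It was the only 1 of 12 such markers with enough counts to test. Fibroblast markers took 0.00948% of counts in CEP and 0.00668% in DMSO, endothelial markers 0.0116% of counts in CEP and 0.00937% in DMSO, lymphocyte markers 6.65e-04% of counts in CEP and 4.84e-04% in DMSO, and adipocyte markers 1.99e-04% of counts in CEP and 1.02e-04% in DMSO. Pdgfra, a growth factor receptor gene in the fibroblast list, rose by 0.52 ± 0.0668, to 94.1 ± 8.04 CPM in CEP from 65.8 ± 3.41 CPM in DMSO. Flt1, in the endothelial list, rose by 0.31 ± 0.0496, to 115 ± 2.89 CPM in CEP from 93.2 ± 3.34 CPM in DMSO. These genes gave nearly all counts of their lists, with 8 of 9 fibroblast and 7 of 8 endothelial markers under 1 CPM. Lck, in the lymphocyte list, rose by 0.45 ± 0.156, a call that ended without CEP replicate 2 or 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0552 and 0.0988), without DMSO replicate 1 or 3 (0.115 and 0.124), with DESeq2 (0.114) and with no low-count filter (0.0546, alternatives 0.0246 to 0.124). Fabp4, in the adipocyte list, rose by 1.12 ± 0.326, not past without CEP replicate 3, DMSO replicate 1 or DMSO replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0694, 0.0603 and 0.0786, alternatives 0.00456 to 0.0786). Replication-dependent histone transcripts, which lack poly(A) tails, had 2 of 23 genes with enough counts to test, and H1f2 rose by 0.91 ± 0.119. These lists had fewer than 3 tested members and were not tested with camera.

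**Figure D3:**
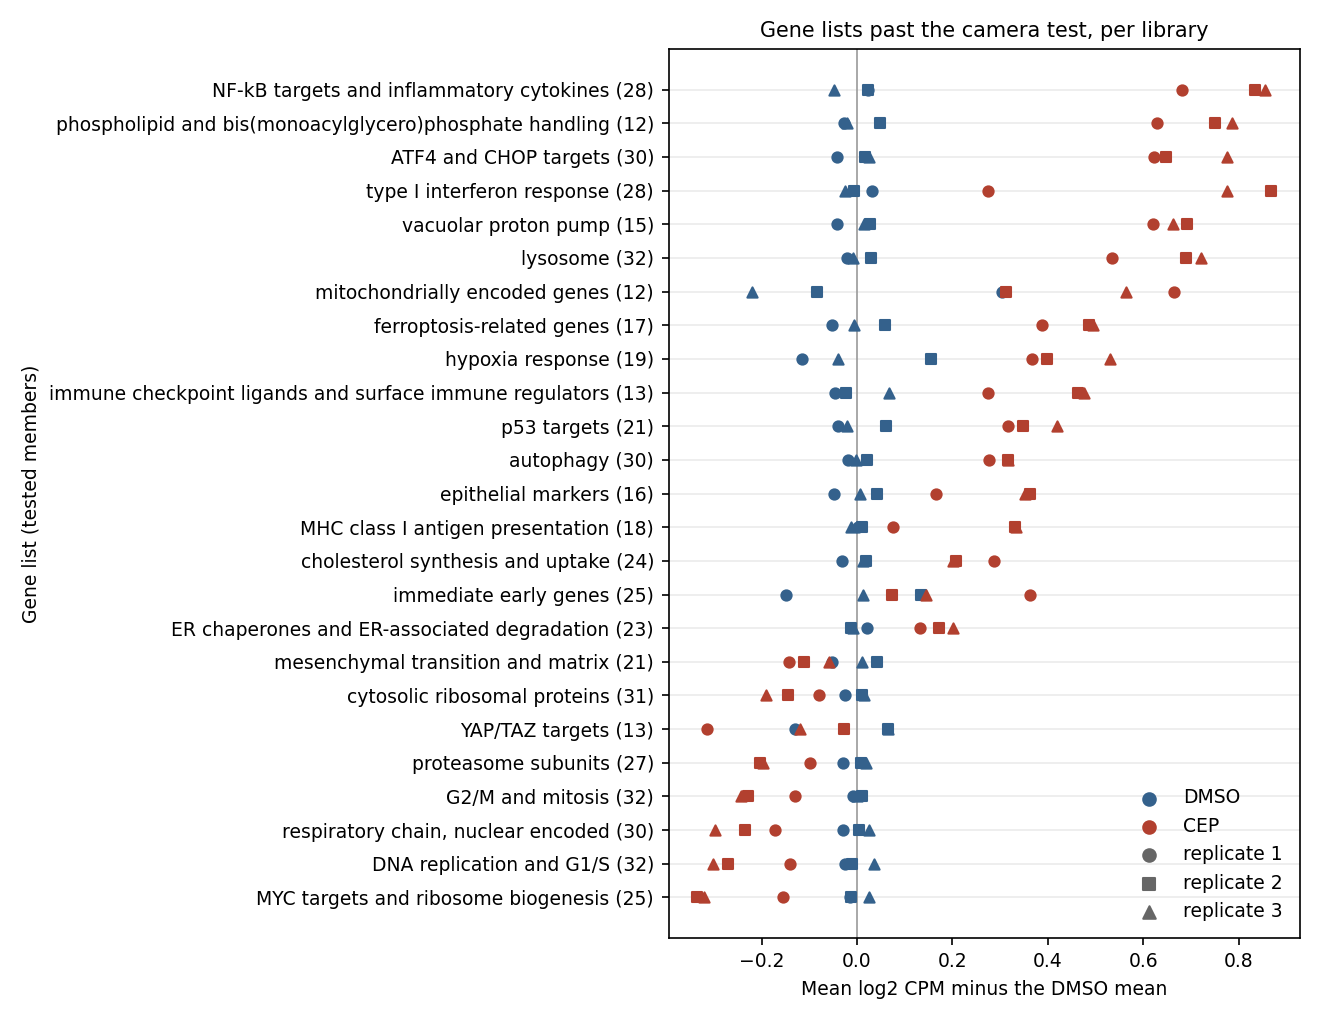
Mean log2 CPM of the tested members of each gene list minus the mean of the DMSO libraries, for the 25 lists past the camera test, with 1 point per library and the number of tested members in parentheses. The CEP and DMSO points overlap for the immediate early and YAP/TAZ lists and separate for the others, and CEP replicate 1 lies nearest to the DMSO libraries for the interferon list (0.27 against 0.87 and 0.78).

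Of 34 lists tested with camera and its preset correlation of 0.01, 25 passed, 17 upward and 8 downward. With the correlation estimated from these libraries 0 passed, although 7 had an unadjusted p under 0.05, and fry and cameraPR gave 28 and 21. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The counting strand was not given in the sources used here, and counts of genes whose exons overlap another gene are uncertain. Among those named, with the overlapping gene in parentheses, these were Acsl3 (Utp14b), Ccnd1 (LTO1), Ccnd3 (Bysl), Cdc25b (Spef1), Cxcl10 (Art3), Cyp51 (Akap9), Ddit3 (Mars, and on the same strand another gene of the symbol Ddit3), Dkc1 (Mpp1), Gbp4 (Gbp8 and Gbp9), Hacd4 (Focad), Hspd1 (Hspe1), Hspe1 (Hspd1), Hyal1 (Hyal3 and Naa80), Map1lc3b (Zcchc14), Ndufs1 (Eef1b2), Npc1 (Rmc1), Pfkp (Pitrm1), Psmb9 (Tap1), Sqstm1 (Mrnip), Tk1 (Afmid), Zan (Ephb4), mt-Nd4 (mt-Nd4l). Exons of predicted, unnamed or small RNA genes overlapped those of Adamts8, Add2, Atp6v0b, Bcl2, Carns1, Ccn2, Ccnd2, Cd274, Cdkn1a, Dnajb9, Dsp, Edn1, Ei24, Elovl6, Ftl1, Gclm, Krt8, Lck, Lilr4b, Mid1ip1, Ncl, Oasl1, Pdgfra, Psma4, Slc2a1, Sorbs3, Tiparp, Tnfsf9, Vcam1 and mt-Co1.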

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

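The settings that left out mitochondrially encoded genes or removed length and GC trends were chosen after the data were seen. Across the other scalings, DESeq2, limma-voom, low-count filters and these settings, 4393 to 5347 genes changed, against 5125, and 23 to 26 lists passed camera with its preset correlation, against 25. At an adjusted p under 0.01 the count of changed genes was 3307, and 4950 changed among protein-coding genes alone. With a mean of at least 5 CPM, 168 genes changed at least 2-fold, against 389, where fewer genes of low level were tested (10412). Upper-quartile factors turned the split from 2691 higher and 2434 lower (52.5% higher) to 2387 and 2960 (44.6%), and lower calls also outnumbered higher ones after removal of length and GC trends (2439 higher, 2592 lower) and without CEP replicate 1 (3391 higher, 3514 lower). The median log2 fold change over the genes of the main test was 0.00831 in that test. It was -0.0225 with upper-quartile factors, -0.00824 after removal of these trends and -0.00452 without CEP replicate 1. Since most changes were small, the split depends on where the scaling sets 0. With DESeq2 that median was also negative (-0.00776), but higher calls still slightly outnumbered lower ones (2203 and 2190). Whether the shift was the whole cause was not tested. Leaving out 1 library at a time gave 3735 to 6905 changed genes and 301 to 659 changed at least 2-fold, both highest without CEP replicate 1. With camera and the estimated correlation 0 lists passed, 7 having an unadjusted p under 0.05, and fry and cameraPR gave 28 and 21. Without the 10 genes with the most counts, the difference in the mitochondrially encoded share was 0.298 percentage points, against 0.869, since mitochondrially encoded genes are among those 10. The list of drug efflux and xenobiotic metabolism, with a median of 0.0382 and a downward camera direction that did not pass, had an upward direction with camera on voom values in the DESeq2 setting (median 0.0487), with limma-voom (0.0135), with cameraPR (0.0382) and without CEP replicate 1 (0.0312), and medians of -0.0974 to 0.0718 with 1 library left out. The glycolysis list, also not past, with an upward direction in the test as reported, turned downward without CEP replicate 1 or DMSO replicate 1, with medians of -0.0463 to 9.88e-04 over the libraries left out. The cause was not tested for either. Of the 5125 changed genes, 6 had the opposite sign after removal of length and GC trends, which covered 13390 of 13405 genes, and 0 had it under any other setting run for genes. No named gene changed sign under any setting. Of the results for named genes under alternatives, 2862 kept their side of the threshold, 86 no longer passed and 3 newly passed. Of those for lists, 623 kept their side, 43 no longer passed, 25 of them with the estimated correlation, 7 newly passed and 6 turned as given for the drug efflux and glycolysis lists. With the replicate number as a block, 4896 genes changed, 387 at least 2-fold, and 25 lists passed. Deviations from the group means correlated at -0.0462, 0.0245 and -0.0354 across genes for libraries of the same number, below the 0.1 that would mark a pairing, and only the libraries numbered 2 correlated best with each other. In the simulation 52% of the smallest changes and 96% of the largest were found. It changed 200 of 13405 genes, against 5125 called here, and drew genes independently. The threshold that the adjustment sets therefore differed, and these shares do not carry over to these data.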

Other observations

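All tests below were chosen after the results they bear on were seen, except the counts over splits of the libraries, and the named members were picked after their values were known. Further gene lists were written after the report's genes had been looked at, from textbook membership, and adjusted over these 7 lists. Their p-values are therefore not independent support for a shift. Nor can they be set beside p-values adjusted over the 34 planned lists, of which 0 passed with an estimated correlation. Genes that sense nutrients at the lysosome surface rose more often than they fell: of 18, 8 rose, 2 fell and 8 did not pass. 9 rose and 2 fell adjusted over the list alone (median 0.21, camera adjusted p = 7.35e-06, adjusted p = 0.0446 with an estimated correlation). Fnip1 and Flcn, of the folliculin complex, rose by 1.20 ± 0.0515 and 1.11 ± 0.0730, and Rragd, a Rag GTPase gene of low level, by 2.30 ± 0.451. Of 10 lipid droplet genes 6 rose, 0 fell and 4 did not pass. 6 rose and 1 fell adjusted over the list alone (median 0.32, camera adjusted p = 5.56e-05, adjusted p = 0.0446 with an estimated correlation). The coat protein genes Plin2 and Plin3 rose by 0.98 ± 0.0580 and 0.86 ± 0.0487. Of 24 genes of endosomal sorting (ESCRT) 10 rose, 3 fell and 11 did not pass, and the list did not pass (10 rose and 3 fell adjusted over the list alone, median 0.04, camera adjusted p = 0.132, adjusted p = 0.317 with an estimated correlation).

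Among lists that fell, 17 of 23 tubulin and actin cytoskeleton genes fell and 0 rose (0 rose and 18 fell adjusted over the list alone, median -0.25, camera adjusted p = 1.00e-07, adjusted p = 0.203 with an estimated correlation), with Tuba1b at -0.60 ± 0.0641 and Actb at -0.51 ± 0.0777. Of 26 mitochondrial ribosomal protein genes 0 rose, 15 fell and 11 did not pass (0 rose and 16 fell adjusted over the list alone, median -0.23, camera adjusted p = 9.72e-06, adjusted p = 0.203 with an estimated correlation). Mrpl12 was at -0.48 ± 0.0552. Of 26 splicing factor genes 1 rose, 16 fell and 9 did not pass (1 rose and 17 fell adjusted over the list alone, median -0.20, camera adjusted p = 1.77e-05, adjusted p = 0.10 with an estimated correlation). Srsf1 was at -0.40 ± 0.0550. Of 17 RAS-ERK output genes 1 rose, 8 fell and 8 did not pass (2 rose and 10 fell adjusted over the list alone, median -0.14, camera adjusted p = 0.00541, adjusted p = 0.342 with an estimated correlation). Dusp6 and Ccnd1 were among those that fell, and Dusp4 was the one that rose. When CEP replicate 1 was left out, 22, 20, 20 and 12 members of the mitochondrial ribosomal, splicing, cytoskeleton and RAS-ERK lists fell.

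The part of the rise in the other CEP libraries that CEP replicate 1 reached differed between gene lists, with medians over members that rose without it from 0.288 for the interferon list to 0.923 for immediate early genes, and above 1 for cholesterol efflux (1.06), fatty acid synthesis (1.11), cholesterol synthesis (1.22) and mitochondrially encoded genes (1.37). On the CPM scale CEP replicate 1 reached a median part of 0.288 of the rise for 33 interferon and MHC class I genes. For 3295 other genes that rose without it the part was 0.575, a gap of 0.286 (95% bootstrap interval over genes 0.173 to 0.362, genes not being independent). Admixture of untreated cells or an evenly weaker response would give equal parts. However, the interferon and MHC class I genes were picked for their low rise in CEP replicate 1. All genes were also called from the CEP libraries that the part is measured against. The interval allows for neither choice, so the gap does not decide between these explanations. Lower depth is argued against by a total 1.20 times the mean of the other CEP libraries. After removal of length and GC trends the gap was 0.279 (0.18 to 0.396), little changed, which argues against such a trend as its whole cause. A first version compared the interferon and MHC class I genes with proton pump and ATF4 genes only, also found a gap, and was replaced after its result was seen. No biological explanation was tested.

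Mitochondrially encoded transcripts rose while nuclear-encoded respiratory chain transcripts fell. With length and GC trends removed, the nuclear-encoded median was -0.21 (SE 0.0194, from -0.23) and the mitochondrially encoded median 0.51 (SE 0.0387, from 0.48). Each SE in this paragraph is that of the list's mean over its genes, treated as independent, and does not measure the spread between libraries. That the medians moved little argues against such trends as the whole cause. Counts taken up by mitochondrially encoded genes could shift all other genes by at most -0.0128 on the log2 scale, from the share of counts left to them, against a nuclear-encoded median of -0.23 (SE 0.0172), which argues against this as the whole cause of that fall. A first version of this test left these genes out of the totals, which moved almost nothing, and was replaced. For the mitochondrially encoded part, a change in the polyadenylation or capture of these transcripts stays open, and no biological explanation of either part was tested.

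Cd68, best known from macrophages, rose by 30.8 CPM. If macrophages among the treated cells were the source, Ptprc, Lyz2, Csf1r, C1qa, C1qb, C1qc, Adgre1 and Itgam could be expected at a similar summed level, but these 8 genes summed to 0.310 CPM in CEP (exact Poisson upper limit 0.503, 16 counts against 13 in DMSO), and Lyz2 had 0 counts in all libraries, which allows 0.0581 CPM in CEP. A first version of this test, which set the ratio of their summed CPM, 1.23 (0.556 to 2.79), beside the Cd68 ratio of 2.78, decided nothing and was replaced. No other explanation of the Cd68 rise was tested.

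Interferon ligand genes were barely counted: 21 such genes had 13 counts in CEP and 12 in DMSO in all, and Ifnb1 had 4 and 1. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave the largest counts, so 1 of 10 splits reached them in each case: 5125 changed genes, 389 changed at least 2-fold and 25 lists, against highest other values of 0, 0 and 19. The other splits gave 57 to 796 genes at an unadjusted p under 0.05 with edgeR, and no other tool was run on them. Each of these other splits sets 2 CEP and 1 DMSO library against 1 CEP and 2 DMSO libraries, so part of the treatment contrast remains in it and the 8 to 19 lists past camera there do not give the number with no effect.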
